A study of Mus musculus with 6 samples.

How the data were processed

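Total RNA from 6 samples of sorted mouse bone marrow cells was measured on 6 Agilent 1-colour arrays, 3 for mice aged 3 months and 3 for mice aged 24 months. Group and replicate number were taken from the sample titles in the labels. The labels record extraction with Trizol and labelling with pCp-Cy3, and neither they nor the design text name the markers used for the sort. Nothing in the labels says that the samples of a group came from separate animals, so the p-values measure the spread between these samples, part of which may be technical.

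Each scanner file holds spot intensities that the authors deposited as Agilent Feature Extraction wrote them. Per the file headers, the software version was 10.7.3.1 and the probe design was annotated on mm9, whereas the submitters' processing notes name version 10.5.1.1. The processed intensity is, per the file headers, background-subtracted and spatially detrended within each array and was not scaled between arrays. The authors also deposited a table of log2 values for 52095 of the 55681 probes. All 52095 were matched by probe identifier, and each column correlated with the log2 processed intensity of its own array at r = 0.9986 to 0.9995 across probes. The medians of its columns, in the order young 1 to 3 and old 1 to 3, were 4.91, 4.92, 4.95, 4.94, 4.92 and 4.87. The method that scaled this table between arrays is not given in the sources used here, and it served as an alternative source of values.

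Control spots were left out, as were spots that the scanner software had marked as outliers, and repeated spots of a probe were averaged. The main values are the log2 processed intensities minus each array's 75th percentile. The files give a RefSeq or other accession per probe and no gene symbol, so symbols were taken from a RefSeq gene table of assembly GRCm38.p6 by accession without version. Of the 55681 probes, 26413 (47.4%) matched a symbol, including 97.9% of the probes with an NM accession, and the others kept the identifier in the files. Coordinates were not used. Each gene name was represented by the probe with the highest mean over all 6 arrays, and a gene was tested when that probe was well above background on at least 3 of the 6 arrays, whatever their group. This left 23280 genes, 13550 of them with a symbol. Of the 5435 genes with more than 1 probe, 9 had probes called in opposite directions. A call is that of the chosen probe, and a further probe of the gene need not have passed. Of the genes named below, Padi4, Anxa1, Timp2, Tgfbr2, Pfkfb3, Foxo1, Gstp1 and Tnfsfm13 had 1 of 2 probes called. Socs2 had 1 of 3 called. The further probes of these genes had fold changes of the same sign.

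Old and young samples were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) without covariates, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. Files were read with Python 3.11.15 and pandas 2.3.3. Of 43 gene lists, 42 had at least 5 tested members. Each was compared with all other tested genes by limma's camera with a preset inter-gene correlation of 0.01, and the p-values were adjusted over the 42 lists. Camera with an estimated correlation and fry served as alternatives, and 20 genes with a spot left out on an array did not enter these tests. For a gene not well above background on any array of a group, the change is given as at least N-fold. The bound applies to the main background correction, and the alternatives can give smaller changes. This bound sets the mean of the measured group against the mean, over the arrays of the other group, of the lowest normalized signal among probes well above background or the gene's own signal, whichever was higher.

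The gene lists, the tests of genes and lists between the ages and the rule for naming genes were fixed before the data were examined. The tests of gene families, cell composition and detection, and some alternatives, were chosen later, as the closing section says. The rule took, in each direction, the 12 genes with the largest change among those past the threshold whose old values all lay outside the range of the young values and whose probe was well above background on all arrays of the higher group, leaving out names that are only clone, region or predicted-gene identifiers. It also took the 4 members with the smallest p of each list past the threshold, the 2 with the smallest p of each other list, and 9 genes whatever their result. Genes named outside this rule are said to have been chosen after their values were seen.

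The steps were tested on simulated data for the comparison of old with young samples. With 200 of 23260 genes changed in each of 5 draws, 59.8% of changes of 1 log2 unit and 88.2% of changes of 2 log2 units were recovered, and 5.25% of the calls were false. With 1 list shifted, 1 of the 42 lists was called, and with none shifted no list was called. The simulated genes were drawn independently of each other, so this run cannot show how the list test behaves when genes are correlated.

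Alternatives covered the background correction, quantile, median and cyclic loess scaling, the filter on dim probes, the choice of probe per gene, the deposited table, the replicate number as a block, the variance model, array weights, spots marked as outliers, and leaving out each array. All 6 arrays lay on 1 slide and were read in 1 scan. The 3 young samples occupied the first slide row and the 3 old samples the second, so slide row and age group cannot be told apart. Precision is limited by the number of arrays.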

Results

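Gene expression was measured in bone marrow cells sorted from C57BL/6 mice of 2 ages, which the labels describe as mesenchymal stem cells of the bone marrow. Mice aged 3 months, called young here, gave 3 samples, and 3 came from mice aged 24 months, called old. The arrays of the old samples were dimmer. The 75th percentile of the processed signal was 376, 393 and 315 in young replicates 1 to 3, and 319, 250 and 229 in old replicates 1 to 3. Of the 55681 probes, 60%, 59.8% and 55.3% were well above background on the young arrays and 53.4%, 52.9% and 50.9% on the old arrays. Across genes, which are not independent replicates, arrays correlated at r = 0.9899 to 0.9947 within the young group, 0.9908 to 0.9921 within the old group and 0.9743 to 0.9895 between the groups. The first principal component, which carried 57.2% of the variance, separated the ages.

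The share of marker genes that could be measured differed between cell types. Of the erythroid list, which includes the globins and enzymes of haem synthesis, 19 of the 20 genes on the array were well above background on all 6 arrays. The same held for 20 of 20 neutrophil genes, 18 of 20 genes shared by all leukocytes, 34 of 34 DNA replication genes and 40 of 40 mitosis genes. Other blood cell lists were measured less completely, with 16 of 22 B cell, 13 of 20 T cell, 6 of 16 NK cell, 15 of 25 monocyte and macrophage, 11 of 16 dendritic cell and 7 of 11 plasma cell genes. Of adipocyte genes 17 of 21 were well above background on all 6 arrays. It held for 11 of 26 genes of mesenchymal and perivascular stroma, 6 of 21 osteoblast and osteocyte genes, 15 of 43 extracellular matrix genes, 5 of 17 cartilage genes, 8 of 25 endothelial genes and 5 of 18 smooth muscle and pericyte genes. Pdgfra and Pdgfrb, which encode the receptors for platelet-derived growth factor, and the mesenchymal transcription factors Prrx1, Twist1 and Foxc1 were not well above background on any array. These 5 genes were picked out after their values were seen. Xist, the transcript of the inactive X chromosome, was well above background on all 6 arrays, and 4 of 4 Y-linked genes did not reach the 3 arrays needed for a test.

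**Figure D1:**
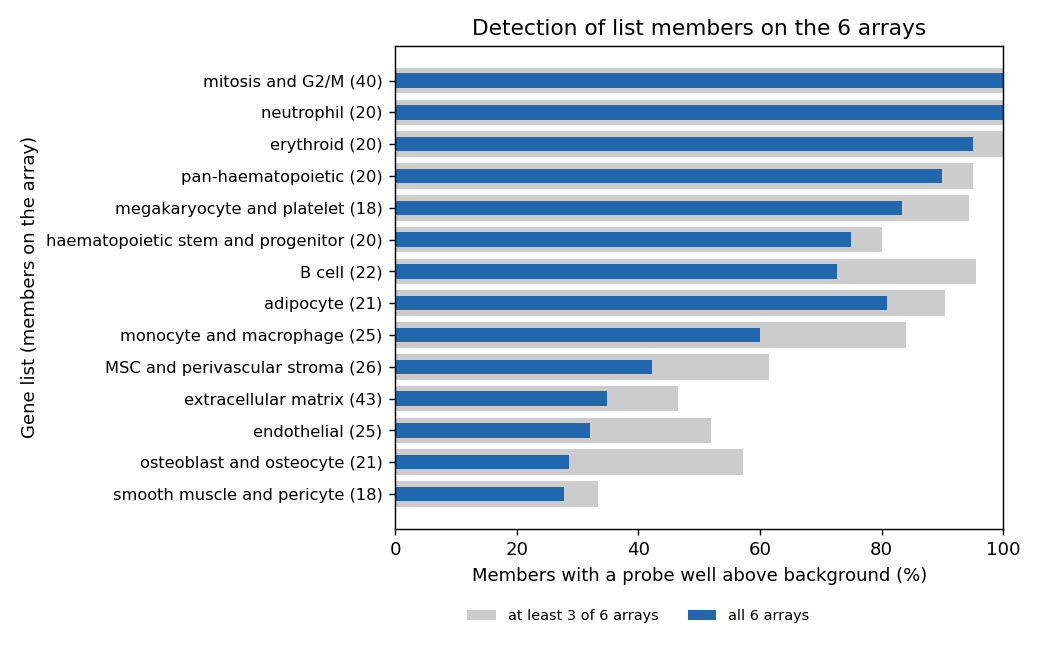
Share of the members of 14 gene lists with a probe well above background, as percent of the members on the array, on at least 3 of the 6 arrays (grey) and on all 6 (blue). Neutrophil and mitosis genes reach 100%, whereas 11 of 26 stromal and 6 of 21 osteoblast genes were well above background on all 6 arrays.

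The comparison of old with young samples asks which transcripts of the sorted cells differ with age. The B cell list fell in 11 of 21 tested members in old samples, the monocyte and macrophage list in 12 of 21 and the dendritic cell list in 7 of 15. With an estimated correlation these lists did not pass (camera adjusted p = 0.303, 0.304 and 0.303). Col1a1 (NM_007742), the main collagen chain of bone, was at least 37.3-fold lower (adjusted p = 0.0222, limma with Benjamini-Hochberg adjustment, n = 3 and 3), and the B cell list had a median log2 fold change of -2.33. Far fewer genes rose by a large factor, among them Dsc2 (NM_013505), a desmosomal cadherin, which was at least 10.8-fold higher (limma adjusted p = 0.0139). Both bounds depend on the processing. The smallest log2 fold changes among the alternatives were -3.22 for Col1a1 and 1.69 for Dsc2. The erythroid list changed in none of its 20 tested members.

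Of 23280 genes tested, 1862 (8.0%) passed the limma threshold after Benjamini-Hochberg adjustment, 924 higher and 938 lower in old samples. Sizes were unequal: 680 genes fell and 128 rose by at least 2-fold, and 217 fell and 6 rose by at least 4-fold. Direction also went with the mean normalized log2 signal. At a signal of -4 or less 113 genes fell and 6 rose, and from -2 to 0 the numbers were 276 and 302. From 4 to 6 only 9 fell and 63 rose, and from 6 to 8 the numbers were 0 and 27. The old arrays were dimmer, so the unequal sizes alone do not show an effect of age. Among genes with a symbol, 730 fell and 400 rose. In 204 of the genes that fell, no old array was well above background, and in 5 of those that rose no young array was. The 2 age groups did not overlap in 8377 genes, or 36.0%, against 10% expected on average for arrays grouped at random. Genes are correlated, so the share for a single grouping can lie far from 10%, and it does not single out age. The share of calls that were higher in old samples was 49.6%, but 39.0% with the deposited table and 61.2% with normexp background correction of the median signals. No gene passed with the replicate number as a block (5556 at an unadjusted limma p under 0.05) or without the filter on dim probes (11662 unadjusted). Every array carried weight in these calls: 63 genes passed without young replicate 2, 5 without old replicate 3 and 1 without old replicate 2, with 310, 765 and 1154 without young replicate 3, young replicate 1 and old replicate 1. The young arrays lay in one slide row and the old arrays in the other, so row and age cannot be told apart.

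Camera placed 25 of the 42 gene lists apart from the other genes, 23 lower and 2 higher in old samples. Splits of the arrays that mixed the ages gave 1 to 24 lists, so this count alone says little about age. None of the 42 lists passed when camera estimated the correlation between genes (4 at an unadjusted p under 0.05, and 14 by fry), so each list that passed is given below with both p-values. The 17 lists that did not pass had adjusted p-values of at least 0.426 with an estimated correlation. Under every scaling tried, with normexp and the deposited values counted among them, 13 of the 25 lists passed. They included the B cell, monocyte, neutrophil, dendritic cell, NF-kB and immediate early genes. The other 12 lost their call under at least 1 scaling: stroma, osteoblast, niche cytokine, BMP, plasma cell, T cell, mast cell, osteoclast, adipocyte, sirtuin, ribosomal and oxidative phosphorylation genes. Only 8 of the 25 lists passed in every setting other than the estimated correlation. Neutrophil genes were not among these, as their fry adjusted p was 0.0601. In the same samples the list of genes shared by all leukocytes had a median log2 fold change of -1.0. It fell in 8 of 19 tested members, and in 15 adjusted over the list alone, among them the leukocyte antigen Ptprc at -1.28 ± 0.24 (log2 fold change ± SE here and below, limma adjusted p = 0.0361), Cd52 at -1.62 ± 0.27 and Cytip at -1.77 ± 0.22. For that list the camera adjusted p was 7.12e-10, and the adjusted p = 0.304 with an estimated correlation. Young replicate 3, looked at because of its values, lay apart from the other young arrays on the first principal component (-59.8 against -26.2 and -30.1). It had the highest signal of the young arrays in 16 of the 19 leukocyte genes, 19 of 20 neutrophil genes and 20 of 21 monocyte and macrophage genes. Ptprc was 0.39, 0.43 and 1.23 in young replicates 1 to 3 (log2 relative to the 75th percentile). Without young replicate 3 the mean of the members minus that of all other genes went from -1.01 to -0.80 for the leukocyte, -1.28 to -1.0 for the neutrophil and -1.52 to -1.21 for the monocyte list, and these lists passed at a camera adjusted p of at most 4.66e-10.

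Scaling and background correction also decided part of the single calls. Normexp is a background correction and was followed by the main scaling. It added an offset of 50 before the log2 step, which shrinks the fold changes of dim genes. Of the 105 calls among the genes chosen by the naming rule, 24 ended and 3 turned direction with normexp, and 8 ended with quantile normalization, 11 with cyclic loess and 8 with the deposited values. With normexp the log2 fold change shrank to -0.01 for Egln1, -0.02 for Il15, -0.04 for Omd, -0.05 for Clec9a, -0.07 for Gpx3, -0.08 for Slamf7 and Klre1, -0.11 for Socs2, -0.15 for Mrc1, -0.17 for Egln3, -0.21 for Tcf7 and -0.27 for Ccn2. It was -0.31 for Cebpa, -0.34 for Klrb1c, -0.36 for Tnf, -0.41 for Arg2, -0.42 for Birc3, -0.46 for Cd209a, -0.48 for Dapl1, -0.51 for Nsg2, -0.57 for Ifit3 and -0.75 for Alox15. All these calls ended, as did those of Wrn (0.34) and Cd8a (0.37). The same 5 calls ended under quantile normalization, cyclic loess and the deposited values alike, at limma adjusted p between 0.0501 and 0.0780. H2-Ob was -1.07, -1.11 and -1.09 with these scalings, against -1.05 with the main settings, and Gzma was -2.35, -2.38 and -2.31 against -2.32, so their folds stayed about as large. Wrn was 0.43, 0.39 and 0.41 against 0.45, Cd8a 0.57, 0.58 and 0.48 against 0.61, and Uqcrc1 0.30, 0.29 and 0.31 against 0.39.

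**Figure D2:**
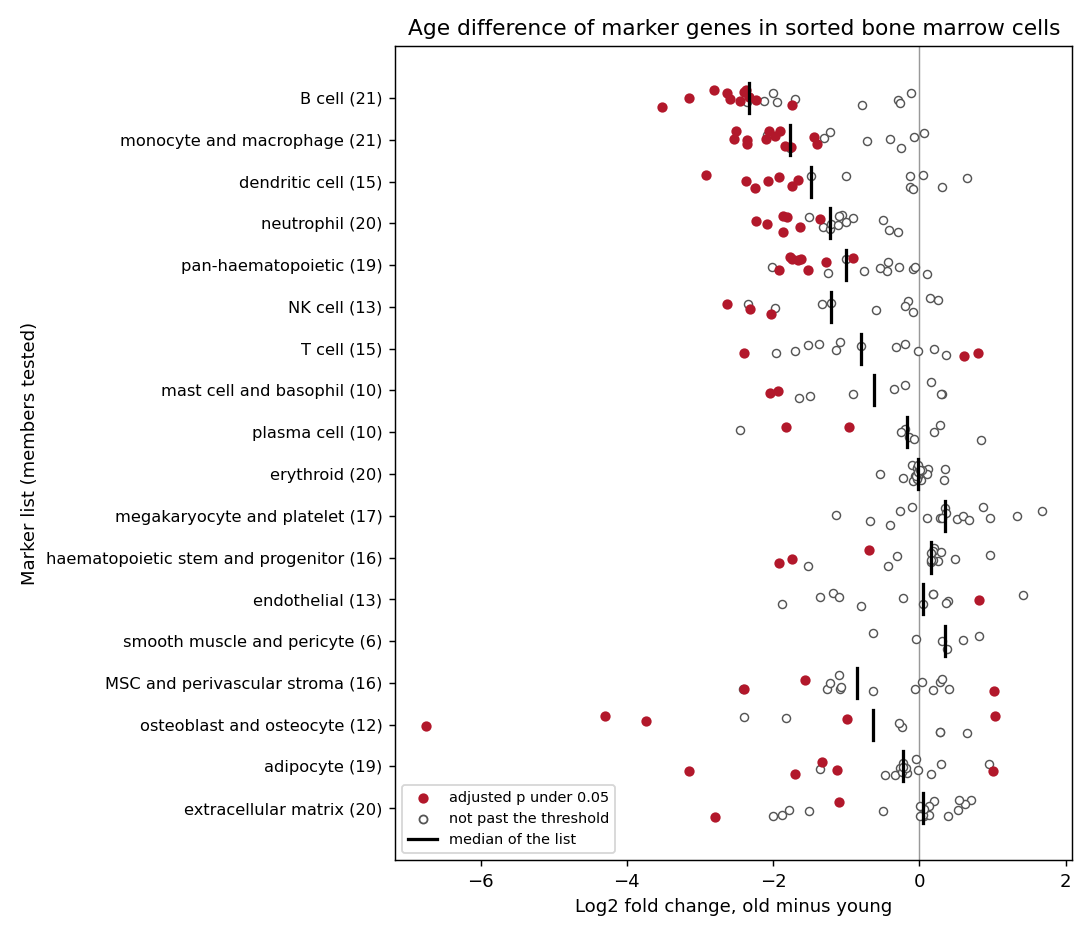
Log2 fold change, old minus young, of the tested members of 18 marker lists, with 1 point per gene; red points passed the adjusted threshold of 0.05, open points did not, and black lines are list medians. The B cell and monocyte lists have medians of -2.33 and -1.77, whereas erythroid genes lie around -0.03; fitted values are drawn also for genes that were not well above background in a group.

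Of 12 tested genes of the osteoblast list, 4 fell, 1 rose and 7 did not pass. Sparc (NM_009242), a matrix glycoprotein of bone, fell by 4.30 ± 0.77 on the log2 scale (limma adjusted p = 0.0320), and Bglap2 (NM_001032298), an osteocalcin gene, by 3.74 ± 0.80 (limma adjusted p = 0.0455; well above background on 2 of 3 old arrays). Omd, which encodes osteomodulin, was at least 1.81-fold lower. Col1a1 had a signal of 1.01 ± 1.59 in young samples (log2 relative to the 75th percentile, mean ± SD, n = 3), and no old array was well above background. The opposite direction was seen for Sp7 (NM_130458), the transcription factor osterix, which rose by 1.03 ± 0.15 (limma adjusted p = 0.0251). Young samples differed among themselves in these genes: the Sparc signal relative to the array's 75th percentile was 3.13, 0.49 and 3.34 log2 units in young replicates 1 to 3 and -1.53, -2.14 and -2.28 in old replicates 1 to 3. Adjusted over the list alone, 6 osteoblast genes were lower and 3 higher. The list's median was -0.64 (-0.57 with 3 genes set to their bound) and its camera adjusted p = 0.0268, against an adjusted p = 0.426 with an estimated correlation. Without old replicate 3 its camera adjusted p was 0.119. The list of genes shared by all leukocytes had a median of -1.0 in the same samples, as it did beside the stromal and niche genes below. Runx2, the osteoblast master regulator, was well above background on 2 arrays of each group and differed by 0.66 ± 0.24 (limma adjusted p = 0.141).

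Cxcl12 (NM_001012477), the chemokine that retains blood stem cells in the marrow, fell by 2.40 ± 0.43 on the log2 scale (limma adjusted p = 0.0326). Lepr (NM_010704), the leptin receptor and a marker of perivascular stroma, rose by 1.02 ± 0.14 (limma adjusted p = 0.0252), and Thy1 fell by 1.56 ± 0.33. The mean normalized log2 signal of Lepr was 3.75 in young and 4.77 in old samples, against -0.81 and -3.21 for Cxcl12. Cd44 of the same list was also bright (3.15 and 3.43). Pdgfra, Pdgfrb, Foxc1 and Grem1 of that list were not well above background on any array. The Lepr rise alone therefore cannot be read as a rise of stromal cells. With cyclic loess the Thy1 value was -1.62 and its limma adjusted p 0.0508, so its call was among the 11 to end without a smaller fold. Of 16 tested stromal genes 2 fell and 1 rose, with 5 lower and 2 higher adjusted over the list alone, and the median was -0.86 (-0.42 with 1 gene at its bound). The stromal list passed narrowly (camera adjusted p = 0.0487; adjusted p = 0.426 with an estimated correlation) and did not pass without young replicate 3 (0.118), old replicate 2 (0.0764) or old replicate 3 (0.107). Among 9 tested cytokines of the blood stem cell niche, Cxcl12 and Il15 (at least 1.25-fold lower, but -0.02 with normexp) fell, as did 3 adjusted over the list alone, with a median of -0.32 (-0.21 with 2 genes at their bound), camera adjusted p = 0.0281 and adjusted p = 0.303 with an estimated correlation. That call ended without old replicate 2 (camera adjusted p = 0.0612), and under normexp the list's direction turned. Extracellular matrix genes as a list did not pass (camera adjusted p = 0.241), with a median of 0.05 and a mean of -0.41. Fibronectin (Fn1) fell by 2.79 ± 0.45 and the metalloproteinase inhibitor Timp2 by 1.10 ± 0.18, and 7 lower and 3 higher members passed adjusted over the list alone. Without young replicate 2 that list passed (camera adjusted p = 0.0344).

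Genes of the B lineage formed the list with the lowest median. Falls were seen for the V(D)J recombinase gene Rag1 (-3.52 ± 0.63), the lineage factor Ebf1 (NM_007897, -3.14 ± 0.30), the pre-B cell gene Vpreb3 (NM_009514, -2.81 ± 0.38), the transcription factor Spib (-2.36 ± 0.29) and the signalling adaptor Blnk (-1.75 ± 0.22), with limma adjusted p between 0.0176 and 0.0326. Rag1 and Ebf1 were well above background on 1 of the 3 old arrays. Il7r, the receptor for the B cell growth factor interleukin 7, also fell, by 3.20 ± 0.58 (limma adjusted p = 0.0326; 2 of 3 old arrays). All 21 tested members had negative fold changes, 11 passed, and 17 passed adjusted over the list alone. The list's camera adjusted p was 8.23e-14, and the adjusted p = 0.303 with an estimated correlation. The plasma cell list was closer to 0, with a median of -0.17 and falls of Mzb1 (-1.82 ± 0.29) and Slamf7 (-0.96 ± 0.20, on 2 of 3 old arrays) among 10 tested members, or 3 adjusted over the list alone. Its camera adjusted p was 0.0396 (adjusted p = 0.426 with an estimated correlation), rising to 0.432 without young replicate 3 and 0.0962 without old replicate 3.

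Myeloid markers fell in several lists, in the samples in which the leukocyte list had a median of -1.0. Among monocyte and macrophage genes, the chemokine receptor Ccr2 (well above background on 2 of 3 old arrays) fell by 2.51 ± 0.37, the pore-forming protein gene Mpeg1 by 2.36 ± 0.29 and Aif1 by 1.91 ± 0.28 on the log2 scale, and the mannose receptor gene Mrc1 was at least 1.66-fold lower (limma adjusted p between 0.0220 and 0.0262). In that list 12 of 21 tested members fell, 15 adjusted over the list alone, with a median of -1.77 (-1.44 with 5 genes at their bound), camera adjusted p = 3.16e-12 and adjusted p = 0.304 with an estimated correlation. Dendritic cell genes fell in 7 of 15 members, 8 adjusted over the list alone. They included the transcription factor Irf8 (-2.37 ± 0.30), the growth factor receptor Flt3 (-1.75 ± 0.17), the lectin receptor Clec9a (at least 1.47-fold lower, but -0.05 with normexp) and Cd209a (at least 2.96-fold lower). The dendritic list had a median of -1.48 (-1.0 with 2 genes at their bound) and a camera adjusted p = 5.64e-06, or an adjusted p = 0.303 with an estimated correlation. All 20 neutrophil genes had negative fold changes, 7 passed, and 20 passed adjusted over the list alone, with a median of -1.22. Mmp8 was 2.94, 3.26 and 4.07 in young replicates 1 to 3, so replicate 3 carried more of this signal. The falls included the granule collagenase Mmp8 (-1.86 ± 0.32), Retnlg (-1.82 ± 0.30), Padi4 (-2.08 ± 0.40) and Anxa1 (-1.63 ± 0.33). The neutrophil list's camera adjusted p was 3.16e-12, and the adjusted p = 0.36 with an estimated correlation. MHC class II genes fell in 3 of 11 members, 8 adjusted over the list alone, with H2-Aa at -1.92 ± 0.39, H2-Oa at -1.38 ± 0.21 and H2-Ob at -1.05 ± 0.23 (camera adjusted p = 1.60e-06; adjusted p = 0.304 with an estimated correlation).

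Immediate early, NF-kB, secreted senescence factor and interferon genes are described here beside the leukocyte list, which had a median of -1.0 in the same samples. Immediate early genes, which respond to stimulation within minutes, fell in 8 of 23 members, 14 adjusted over the list alone, including Fos (-1.75 ± 0.19), Fosl2 (-2.29 ± 0.37, on 2 of 3 old arrays), the phosphatase Dusp2 (-1.87 ± 0.15) and Klf4 (-1.21 ± 0.18). Their median was -0.93, with camera adjusted p = 5.17e-10 and adjusted p = 0.303 with an estimated correlation. The NF-kB list fell in 6 of 23 members, 10 adjusted over the list alone, with a median of -1.08 and falls of the pattern receptor Tlr2 (-2.10 ± 0.31), Nfkbiz (-1.36 ± 0.23) and Birc3 (-1.17 ± 0.21). Its camera adjusted p was 3.04e-07, and the adjusted p = 0.303 with an estimated correlation. Of 42 factors known to be secreted by senescent cells, 17 could be tested. Of these 5 fell, 6 adjusted over the list alone, none rose and 12 did not pass, with positive values for Tgfb1 (0.23), Igfbp2 (0.26) and Igfbp6 (0.15). The falls included Tnf (-1.46 ± 0.24) and Ccl2 (-1.37 ± 0.17), both on 2 of 3 old arrays, and Ccl3 (-2.10 ± 0.39) and Plaur (-2.01 ± 0.39), and the median was -0.39. For these factors the camera adjusted p was 0.000249, but the adjusted p = 0.353 with an estimated correlation and 0.0971 by fry. Interferon response genes had a median of -0.20, with 2 of 38 members past the threshold (Ifit3 at -2.0 ± 0.37, on 1 of 3 old arrays, and Oas2 at -1.55 ± 0.29) and also 2 adjusted over the list alone (camera adjusted p = 0.000581; adjusted p = 0.526 with an estimated correlation).

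The senescence regulator Cdkn2a (p16 and p19Arf) and the cytokine Il6 were not well above background on any array. Cdkn1a (p21) differed by -0.49 ± 0.15 without passing (limma adjusted p = 0.0955). The senescence and p53 list did not pass (camera adjusted p = 0.238, and 0.0431, lower, with no filter on dim probes), with a median of 0.01 and a mean of -0.15, and 1 of its 23 tested members fell, also 1 adjusted over the list alone. That member was the chromatin protein gene Hmga2 (limma adjusted p = 0.0335), whose direction turned with normexp (0.077). Its tested probe was not well above background on any old array. Another of its probes was, so neither a bound nor a fold is given.

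Fat, growth factor and cytoskeletal genes changed in part, with the leukocyte list at a median of -1.0 in the same samples. In the adipocyte list the transcription factor Cebpa fell by 1.12 ± 0.17 on the log2 scale and Cfd, which encodes adipsin, was at least 1.41-fold lower (its direction turned with normexp, to 0.035), whereas Lep, the leptin gene, rose by 1.0 ± 0.15. Pparg differed by -0.22 ± 0.12 without passing (limma adjusted p = 0.270). Of 19 adipocyte genes 4 fell, including Ebf1, which is also in the B cell list, and 1 rose, the same numbers as adjusted over the list alone, with a median of -0.23, camera adjusted p = 0.00482 and adjusted p = 0.303 with an estimated correlation. BMP and TGF-beta genes fell in 6 of 26 members and rose in 1, again the same numbers adjusted over the list alone, with Tgfbi at -2.16 ± 0.35, Id2 at -1.56 ± 0.28, Tgfbr2 at -1.03 ± 0.21 and the BMP antagonist Nog at 1.15 ± 0.09 (camera adjusted p = 0.0215; adjusted p = 0.303 with an estimated correlation). Cytoskeletal genes fell in 4 of 23 members, with 7 lower and 2 higher adjusted over the list alone, among them Vim (-1.74 ± 0.29), Tpm4 (-2.05 ± 0.32), Flna (-0.39 ± 0.08) and the matricellular gene Ccn2 (at least 1.78-fold lower). That list's camera adjusted p was 0.00125, and the adjusted p = 0.303 with an estimated correlation. Glycolysis and hypoxia genes had a median of 0.01 and a mean of -0.28, with falls of 5 of 30 members, or 6 lower and 1 higher adjusted over the list alone, including the prolyl hydroxylases Egln3 (at least 1.63-fold lower; -0.17 with normexp) and Egln1 (-0.52 ± 0.11; -0.01 with normexp), Pfkfb3 (-0.92 ± 0.14) and Adm (at least 1.12-fold lower, but 0.10 with normexp). Its camera adjusted p of 0.0376 (adjusted p = 0.561 with an estimated correlation) became 0.0683 without young replicate 2, 0.0930 without young replicate 3 and 0.107 without old replicate 3. The Wnt list did not pass (camera adjusted p = 0.726), with a median of 0.10 and a mean of -0.14. Its members Lef1 (-2.74 ± 0.60, on 1 of 3 old arrays) and Tcf7 (at least 1.84-fold lower) fell, and 2 lower and 3 higher members passed adjusted over the list alone.

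Lymphoid and other blood cell lists did not all follow the B cell and myeloid genes. T cell genes went both ways, with rises of the receptor chain Cd3e (0.80 ± 0.13) and of 1 of the 2 probes of Cd8a (0.61 ± 0.13) beside a fall of the homing receptor Ccr7 (-2.40 ± 0.47). Adjusted over the list alone, 7 lower and 4 higher of the 15 passed. The list's median was -0.80, with camera adjusted p = 0.0313 and adjusted p = 0.640 with an estimated correlation, and without young replicate 3 or old replicate 2 the camera adjusted p was 0.142 or 0.0542. NK cell genes fell in 3 of 13 members, 6 adjusted over the list alone, with Gzma at -2.32 ± 0.51, Klrb1c at least 2.91-fold and Klre1 at least 1.78-fold lower, and a median of -1.21 (-0.83 with 2 genes at their bound; camera adjusted p = 0.000979, adjusted p = 0.426 with an estimated correlation). Mast cell and basophil genes fell in 2 of 10 members, also 2 adjusted over the list alone, namely Cpa3 (-2.04 ± 0.41) and Hdc (-1.93 ± 0.38), with camera adjusted p = 0.0329 and adjusted p = 0.426 with an estimated correlation. Leaving out young replicate 3, old replicate 1 or old replicate 3 gave 0.0733, 0.0561 and 0.0896. In the osteoclast list Mmp9 alone fell (-2.23 ± 0.46) among 10 members, 4 adjusted over the list alone, with camera adjusted p = 0.0376 (adjusted p = 0.426 with an estimated correlation), 0.110 without young replicate 3 and 0.0607 without old replicate 3. Mmp9 is also in the neutrophil and secreted factor lists, so its fall is not particular to osteoclasts. Blood stem and progenitor genes did not pass as a list (camera adjusted p = 0.305; median 0.16, mean -0.22), although 3 of 16 fell, among them Cd93 (-1.92 ± 0.19) and Flt3, with 4 lower and 1 higher adjusted over the list alone.

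With the main settings no list test passed for the erythroid (median -0.03, camera adjusted p = 0.392), megakaryocyte (median 0.35, 0.726), endothelial (median 0.05, mean -0.24, 0.555), smooth muscle (median 0.34, 0.481), Schwann cell (median 0.06, 0.999), skeletal muscle (median 0.18, 0.720) or cartilage genes (median 0.11, mean -0.08, 0.860). Pecam1 of endothelial cells differed by -0.22 ± 0.08 (limma adjusted p = 0.156). Within these lists 1 of 2 probes of the VEGF receptor Kdr (0.81 ± 0.16) and the calcium buffer Pvalb (0.79 ± 0.10) rose. The mean normalized log2 signal of this Kdr probe was 4.64 in young and 5.46 in old samples, against -1.37 and -1.59 for Pecam1. The endothelial genes Tie1 and Emcn were not well above background on any array. The Kdr rise alone therefore cannot be read as a rise of endothelial cells. No member passed in the erythroid, megakaryocyte, smooth muscle, Schwann cell or cartilage list, also adjusted over each list alone. Adjusted over the list alone, 1 endothelial gene was higher, and of the skeletal muscle genes 2 were higher and 1 lower.

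Genes of growth and protein synthesis differed little in size. All 50 ribosomal protein genes had positive fold changes, with a median of 0.26, yet none passed singly, also adjusted over the list alone (camera adjusted p = 3.57e-08; adjusted p = 0.426 with an estimated correlation). The middle 95% of random lists matched on mean signal had medians from 0.22 to 0.28, which placed the ribosomal list at percentile 80.2 of 10000 lists, and quantile normalization turned the direction of its camera test. Oxidative phosphorylation genes had a median of 0.14 (camera adjusted p = 0.00125; adjusted p = 0.398 with an estimated correlation), at percentile 64.0 of matched lists, and 1 of 46, Uqcrc1 (0.39 ± 0.08), rose, with none adjusted over the list alone. DNA replication (median -0.02, camera adjusted p = 0.197), mitosis (median -0.04, 0.0987), DNA repair (median -0.02, 0.121), protein folding (median 0.13, 0.199), oxidative stress defence (median 0.06, mean -0.03, 0.720) and IGF axis genes (median 0.04, mean -0.03, 0.555) did not pass. DNA replication genes did pass, lower, with normexp (camera adjusted p = 0.000202), quantile normalization (0.00365), cyclic loess (0.0128), the deposited values (0.0235) and no filter on dim probes (0.0231). Mitosis genes passed, lower, with normexp (0.000246), quantile normalization (0.0220), cyclic loess (0.0210), no filter (0.00711), probes above background on all 6 arrays (0.0400), and without young replicate 1 (0.0199) or old replicate 1 (0.0274). DNA repair genes passed, lower, with normexp (0.00107) and no filter (0.00911), erythroid genes, lower, with normexp (0.00972), and protein folding genes, higher, without old replicate 3 (0.0134). DNA replication, mitosis and erythroid genes lay at percentiles 0.02, 0.1 and 0.13 of lists matched on signal. Single members changed: Wrn, the Werner helicase gene, rose by 0.45 ± 0.10 (none passed adjusted over the list alone) and Gstp1 by 0.43 ± 0.08, the peroxidase gene Gpx3 was at least 1.29-fold lower, and Socs2 was at least 1.59-fold lower. Genes of sirtuins, telomeres and autophagy had a median of -0.07 and a fall of Foxo1 (-0.84 ± 0.13), the 1 of 31 members to pass, also adjusted over the list alone (camera adjusted p = 0.0422; adjusted p = 0.303 with an estimated correlation). The camera adjusted p of that list was 0.0682, 0.0930, 0.0849 and 0.0841 without young replicates 2 and 3 and old replicates 1 and 2.

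Other genes with large falls were not well above background on any old array, so their falls too are lower bounds under the main background correction. With normexp the calls of Alox15 (log2 fold change -0.75), Nsg2 (-0.51), Dapl1 (-0.48) and Arg2 (-0.41) ended. The smallest log2 fold changes of Ankrd33b and Col5a3 among the alternatives were -1.04 and -0.47. They were Ankrd33b (at least 6.08-fold lower), Alox15, an arachidonate lipoxygenase gene (at least 4.25-fold), the collagen chain gene Col5a3 (at least 3.89-fold), the arginase gene Arg2 (at least 3.23-fold), Nsg2 (at least 2.78-fold) and Dapl1 (at least 2.55-fold), with limma adjusted p between 0.0176 and 0.0380. Aspa, the aspartoacylase gene, was at least 7.17-fold higher (limma adjusted p = 0.0222) and, like Dsc2, well above background on no young array, so the sizes of these rises cannot be ranked. The smallest log2 fold change of Aspa among the alternatives was 1.18. The homeobox gene Hoxb2, well above background on all 6 arrays, rose by 2.47 ± 0.17 (limma adjusted p = 0.0139). The neighbouring apolipoprotein L genes Apol10a and Apol10b rose by 2.28 ± 0.36 and 2.08 ± 0.33. Adgrg7, an adhesion G protein-coupled receptor gene, rose by 1.61 ± 0.22, Ammecr1 by 1.5 ± 0.19, Rprl2 by 1.35 ± 0.23, the anion channel gene Lrrc8b by 1.32 ± 0.21, the phospholipase gene Pla2g4c by 1.29 ± 0.20 and Tnfsfm13 by 1.27 ± 0.09, and the vomeronasal receptor gene Vmn2r62 was at least 2.31-fold higher.

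**Figure D3:**
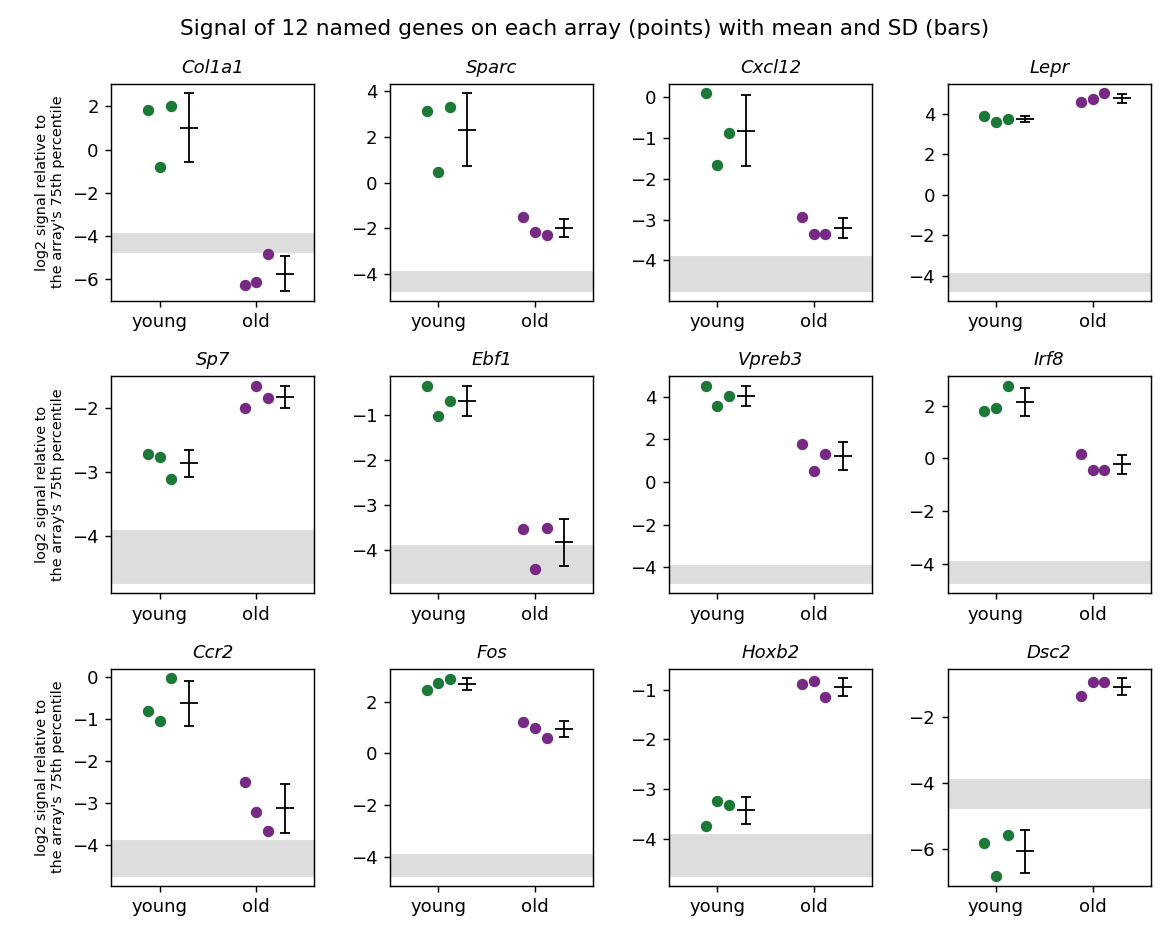
Signal of 12 named genes on each array, as log2 relative to the array's 75th percentile, with 1 point per sample (green young, purple old), and beside them the mean with its SD (n = 3). The grey band spans, over the 6 arrays, the lowest signal among probes well above background (-4.74 to -3.92); all old Col1a1 values and all young Dsc2 values lie below it.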

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

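Normexp on the median signals, the pair of arrays of equal brightness and the lowest-mean probe of each gene were chosen after seeing the data; the other alternatives were planned. The planned normexp on mean signals was not run because the files used here have no such column, and the version on median signals was fitted on the non-control probes. No block for slide or scan was possible because all arrays shared 1 slide and 1 scan. Of 105 named genes past the threshold 100 were never reversed, and of 25 such lists 23 were not, but none of them stayed past the threshold in every setting; the cause was not tested except where stated. Signal over background limits the dim genes, since 204 genes fell with no old array well above background. With the replicate block, 0 genes passed in either direction by limma (5556 at an unadjusted p under 0.05), which has fewer residual degrees of freedom, and no filter on dim probes gave 0 (11662 unadjusted). Pairing the samples by number had no support in the values, as the deviations from group means correlated across genes at -0.03, 0.02 and -0.0074 for equal numbers and up to 0.108 for unequal numbers. The count of genes changed with age, 1862, became 2808 with normexp (1718 higher), 3265 with trend and robust variance (1896 higher) and 808 with a minimum 2-fold change (128 higher), and 593 genes were higher with the deposited values. Leaving out each array gave 1 to 1154 changed, 0 to 558 higher and 1 to 596 lower genes, with 1 changed gene without old replicate 2 and 5 without old replicate 3. The number of lists went from 25 to 16 with quantile normalization, 16 with the deposited values, 0 with camera's estimated correlation (4 at an unadjusted p under 0.05) and 14 with fry, and 18 to 26 on leaving out each array.

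Directions turned as follows, given as log2 fold changes of genes and, for lists, as the mean log2 fold change of the members minus that of all other genes. For a list the direction is that of its camera test, so this value need not change sign. With normexp Cfd was 0.035, Hmga2 0.077, Igfbp4 0.052, Adm 0.10, Cldn5 0.042 and Cdkn1a 0.10, and the list values were 0.087 for cartilage, 0.076 for IGF, -0.060 for oxidative stress, -0.022 for protein folding, -0.050 for niche cytokines and 0.00037 for endothelial genes. With quantile normalization oxidative stress was -0.084 and ribosomal proteins 0.033, with cyclic loess cartilage -0.061, oxidative stress -0.070 and Schwann cell 0.061, and with the deposited values oxidative stress -0.047 and Schwann cell 0.042. With no filter oxidative stress was -0.13, megakaryocyte 0.22, smooth muscle -0.027 and Schwann cell -0.21, and with all 6 arrays above background cartilage was 0.060, endothelial 0.0065 and Schwann cell 0.0058. The mean of a gene's probes gave Cd8a -0.35, Kdr -0.055 and Gfap -0.0023, and the lowest-mean probe gave Cd8a -1.31, Kdr -0.92, Gfap -0.31 and Wnt genes -0.20, since it is another probe of these genes. Trend and robust variance gave Schwann cell 0.052, array weights cartilage -0.043, and fry, with the mean log2 fold change of the members alone, cartilage -0.084 and endothelial -0.24. On leaving out each array, the values ranged from -0.14 to -0.013 for cartilage (turned without young replicate 3 and old replicate 1), from -0.092 to 0.0021 for oxidative stress (young replicate 1), from -0.023 to 0.69 for megakaryocyte (young replicate 3 and old replicate 1) and from 0.0075 to 0.084 for Schwann cell genes (young replicate 1 and old replicate 2).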

Other observations

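The tests of gene families, of cell composition and of detection were chosen after the results were seen; the splits of the samples were planned. The pair of arrays of equal brightness was chosen after the brightness of the arrays was seen and before the values of the pair were, although the family medians were known when the olfactory receptors were tested. The genes named in the next sentences as examples of families were chosen after their values were seen. Among 25 gene families compared with the other genes by Fisher's exact test (Benjamini-Hochberg adjusted over both directions; genes are not independent), genes whose symbol starts with Il and a digit held 17 falls and 2 rises among 49 tested genes (adjusted p = 1.45e-08 for falls). Most encode interleukins or their receptors, but Il4i1, an amino acid oxidase gene among the falls (-0.79 ± 0.16), does not. The falls included Il6ra, a chain of the interleukin 6 receptor (-1.72 ± 0.24), Il1r2 (-1.95 ± 0.33) and Il18r1 (at least 3.87-fold lower). Chemokines and their receptors held 10 falls among 30 genes (adjusted p = 5.44e-05), such as Ccl9 (-1.90 ± 0.28) and the neutrophil receptor Cxcr2 (-1.86 ± 0.38). Semaphorins and plexins held 5 falls among 16 (adjusted p = 0.00938), and Toll-like receptors 3 among 8 (0.0356). C-type lectins held 5 falls and 1 rise among 20 (0.0196), with a median of -0.34 that became 0.10 with normexp. The leukocyte list had a median of -1.0 in the same samples.

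Families with small rises were of another kind. Of 208 tested olfactory receptor genes 15 rose and 1 fell (adjusted p = 0.00938 for rises, Fisher's exact test), with a median of 0.21, and of 302 zinc finger genes of the Zfp series 23 rose and 4 fell (adjusted p = 0.000540), with a median of 0.09. Probes for genomic regions rose in 253 of 3284 cases (7.70%) and fell in 49 (1.49%), whereas genes with a symbol rose in 2.95% (400 genes) and fell in 5.39%. With normexp and cyclic loess, 455 and 177 region probes and 718 and 279 genes with a symbol rose. The median of all genes was 0.07, so the zinc finger genes lay close to it, with 18 rises under cyclic loess and 35 under normexp. The count of olfactory receptors that rose ranged from 9 with the deposited values to 31 with normexp. The ribosomal, oxidative phosphorylation, DNA replication, mitosis and erythroid lists were also set against random lists matched on signal as a test of array brightness; after the outcome was known these were kept as values beside the lists rather than weighed here.

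In old samples 11 of 21 B cell, 12 of 21 monocyte and macrophage, 7 of 20 neutrophil and 7 of 15 dendritic cell genes fell. The 4 lists passed by camera with its preset correlation but not with an estimated one (adjusted p = 0.303, 0.304, 0.36 and 0.303). All genes called lower from 4 arrays, not only members of these lists, were compared in a held-out pair of nearly equal brightness (old 1 minus young 3). The difference there was 1.12 times that in the 4 arrays (95% bootstrap interval over genes 1.09 to 1.17, 404 genes). This interval does not measure the spread between arrays. Young replicate 3 was the highest young array in 19 of 20 neutrophil and 20 of 21 monocyte genes, which could raise the ratio. For these 404 genes as a set the ratio argues against dim arrays as the whole source, but it rests on 1 pair. Of 77 members of the 4 lists 96.1% lay below the median of all genes, but the lists were picked because they fell, so this supports no explanation. B cell members differed by -2.23 in log2 medians from T, NK, megakaryocyte and progenitor members, and by -1.39 from T and NK members alone, whose median was -0.94; as the B cell list was picked as the lowest, this excludes nothing. A smaller share of these cells, fewer leukocytes of every kind, lower expression within the cells, age and slide row all stay open and may each contribute.

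Genes called higher were tested in the same way. The difference in the held-out pair was 0.661 times that in the 4 arrays (bootstrap interval over genes 0.557 to 0.839, 72 genes). The rises were smaller in this pair of nearly equal brightness, so a part that comes from dim arrays stays open. In this 1 pair the ratio argues against dim arrays as the whole source. Young replicate 3 lay apart from the other young arrays on the first principal component, which could raise the ratio here too. Genes are not independent replicates, so the interval does not measure the spread between arrays. For the 208 olfactory receptors the ratio was 0.413 with an interval of -0.0131 to 0.723, so dim arrays and age cannot be told apart for this family. For all these genes age stays open and untested.

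Few markers of stromal and bone cells were well above background, in samples that the labels describe as mesenchymal stem cells. Of the erythroid and shared leukocyte genes 92.5% were well above background on all 6 arrays, against 35.6% of stromal, osteoblast and matrix genes, a difference of 56.9 percentage points between lists picked after their detection was seen. Over all 13 blood cell lists and 6 lists of stromal and skeletal cells and matrix the shares were 71.9% and 40.3%, a difference of 31.6 points (95% interval 21.7 to 41.5). On at least 3 arrays the difference was 44.2 points in the picked lists and 31.7 in all of them. Among genes with at least 2 probes it was 44 and 29.6 (10.5 to 48.7) on at least 3 arrays, so needing a further probe moved it little. Silent probes stay open for part of it, as the lists were picked and the interval is wide. RNA mostly from blood-forming cells may also contribute, with Hba-a2 at 10.15 ± 0.19 in young and 10.50 ± 0.11 in old samples (log2 relative to the 75th percentile, SD, n = 3), but the series' design text does not name the markers of its sort, and low expression of these genes in the sorted cells stays open.

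The 6 samples form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1862 genes against at most 0 in the others, and 924 higher and 938 lower genes against 0 (limma). It gave 25 lists against at most 24. In each of these 4 results 1 split, the real one, gave as large a result.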
